A study of Homo sapiens with 8 samples.

How the data were processed

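RNA sequencing was done on 8 samples of the HEL cell line, 4 with FGF12 overexpression and 4 named NC, after poly(A) selection of total RNA, per the labels' protocols. The groups and the replicate numbers were taken from the sample titles. The authors deposited a table of 20036 genes with a whole-number read count for each gene and sample, without normalization. The same deposited table gives FPKM, the count scaled to gene length and to the total of the sample, and a gene length. Recomputing FPKM from each count, the deposited length and the sum of the counts of that sample gave the deposited value to within a relative gap of 3.66e-07, so the FPKM add no normalization beyond depth and length. Reads were trimmed with fastp 0.22.0 and the genome build was GRCh38, per the submitters' processing notes. The aligner, the counting program, the use of strand and the annotation release are not given in the sources used here. How reads in overlapping or near-identical genes were assigned is therefore not known, and the counts of such genes are uncertain, among them HSPA1A with HSPA1B and HBG1 with HBG2.

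Gene biotypes, exon overlaps and GC content were taken from GENCODE release 29 by Ensembl identifier, which matched 19852 genes, of which 19739 are protein-coding there. No symbol is given for 629 genes. Coordinates are those of the deposited table. Totals ran from 11488466 to 15817220 counts per sample, and 13480 to 13724 genes had at least 1 read. Each pair of libraries within a group differed by more than sampling noise in a chi-square comparison of counts (chi-square per degree of freedom from 1.52 to 4.89), so none were merged.

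Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 11237, libraries were scaled by TMM, and the quasi-likelihood test with robust dispersion estimates compared the 2 groups without a term for the replicate number. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. Values in single genes are given as FPKM with SD over 4 samples. FGF12, at 0 in all NC libraries, has a lower bound in place of a fitted fold, computed from pooled, TMM-scaled CPM against 3 reads over the NC group. Single measures were compared by exact permutation over the 70 assignments.

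In the choice of genes named in the text, fixed before the data were examined, FGF12 and F12 came first. Next came the 10 largest rises and 10 largest falls among protein-coding genes with an adjusted p under 0.05, a mean of at least 1 FPKM in the higher group and no overlap between the groups. Up to 3 members of each list with the smallest adjusted p completed the choice. Genes used for sexing were left out, and 2 of the chosen list members are not reported here. The 30 lists held 795 entries, of which 762 matched the table, and were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2. Lists needed at least 3 tested members. Camera was repeated with an estimated correlation and with fry. FGF12 was kept out of its family's list. Biological process terms of the Gene Ontology with 10 to 200 tested genes were tested in the same way.

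The procedure was tested on simulated data with the means and library sizes of these samples. On 11169 simulated genes, edgeR recovered 66.0% of those changed 1.2-fold, 90.0% of those changed 1.5-fold, 98.0% of those changed 2-fold and all of those changed 4-fold, and 4.95% of its calls were false. Camera called both planted lists and 0 of 28 unchanged ones. The simulation changed 47 to 50 genes at each fold and drew every gene independently, whereas 71.9% of the genes tested were called in the data. Recovery and the share of false calls depend on that fraction, so these rates need not hold for the data. The unchanged lists were random genes without correlation, while estimated correlations in the fixed lists reached 0.784. They do not test camera on correlated lists.

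The alternatives were the replicate number as a block, each sample left out in turn, no filter and a stricter filter of 5 FPKM in 4 samples, DESeq2 1.42.0, DESeq2 size factors in edgeR, limma on log2(FPKM + 1) of genes with at least 1 FPKM in 4 samples, pseudocounts of 0.1 and 0.01, quantile normalization, TPM recomputed from FPKM, a 2-fold minimum, a test against a 1.5-fold threshold and protein-coding genes only. Scaling to total counts, TMM without mitochondrial genes and offsets for GC content and gene length, fitted per library by lowess, were added after the data were seen. Figures were drawn with matplotlib.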

Results

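HEL is a human erythroleukaemia cell line, derived from an acute myeloid leukaemia with erythroid and megakaryocytic features. The study compared HEL cells made to overexpress FGF12 with control cells named NC, to describe the molecular landscape of the overexpressing cells. FGF12 encodes an intracellular FGF homologous factor, a protein that binds voltage-gated sodium channels and is not known as a secreted ligand. Poly(A)-selected RNA was sequenced from 8 samples, 4 per group. Gene counts summed to 13402396 to 15817220 reads in the FGF12 libraries and 11488466 to 14326070 in the NC libraries (exact two-sided permutation test, p = 0.257). The labels do not say that the 4 samples of a group came from separate cultures, clones or lines. All p-values therefore measure only the spread between these samples, which may be technical.

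The overexpressed gene separated the groups completely. FGF12 (ENSG00000114279, GRCh38 chromosome 3, 192139390 to 192767764, minus strand, protein-coding) had 1274, 1451, 1183 and 1086 reads in the FGF12 libraries and 0 reads in each of the 4 NC libraries. Its level was 7.97 ± 0.518 FPKM, or 86.7 ± 5.63 CPM (SD, n = 4). The FPKM divides by the deposited gene length of 10879 bases. It would be too low if the overexpressed transcript was shorter, which was not examined. By CPM, which is not scaled to gene length, FGF12 stood above 75.3% of the genes tested. Pooled over the group and scaled by TMM it stood at 88.7 CPM, against a floor of 0.0574 CPM for 3 reads over the NC group, and was at least 1543-fold higher (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 samples can give). Such floors cover counting error only. The sample names use the symbol F12, which also belongs to the coagulation factor XII gene. That gene stood at 0.254 ± 0.0912 FPKM in the FGF12 libraries and 0.259 ± 0.107 FPKM in NC (SD, n = 4), a log2 difference of 0.08 ± 0.30 (SE) that did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.816).

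The comparison of the FGF12 cells with NC asked how the transcriptome of HEL cells differed with FGF12 overexpression. Ribosome biogenesis genes were higher in the FGF12 cells, where 22 of 27 rose, with NOLC1, which encodes a nucleolar phosphoprotein, at 142 ± 0.852 FPKM against 79.8 ± 1.55 FPKM (SD, n = 4). HSPA8, a constitutive HSP70 chaperone gene, rose from 185 ± 2.14 FPKM to 693 ± 15.1 FPKM, although the fixed list that holds it was not called. Targets of the transcription factor ATF4, which serve amino acid supply and the integrated stress response, were lower, with the cystine transporter gene SLC7A11 at 8.18 ± 0.240 FPKM against 34.6 ± 0.368 FPKM. The kinase gene PIM1, a STAT5 target and one of the abundant transcripts of these cells, fell from 1220 ± 11.4 FPKM to 300.2 ± 5.42 FPKM. The transferrin receptor gene TFRC rose from 33.9 ± 0.960 FPKM to 98.8 ± 1.68 FPKM.

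**Figure D1:**
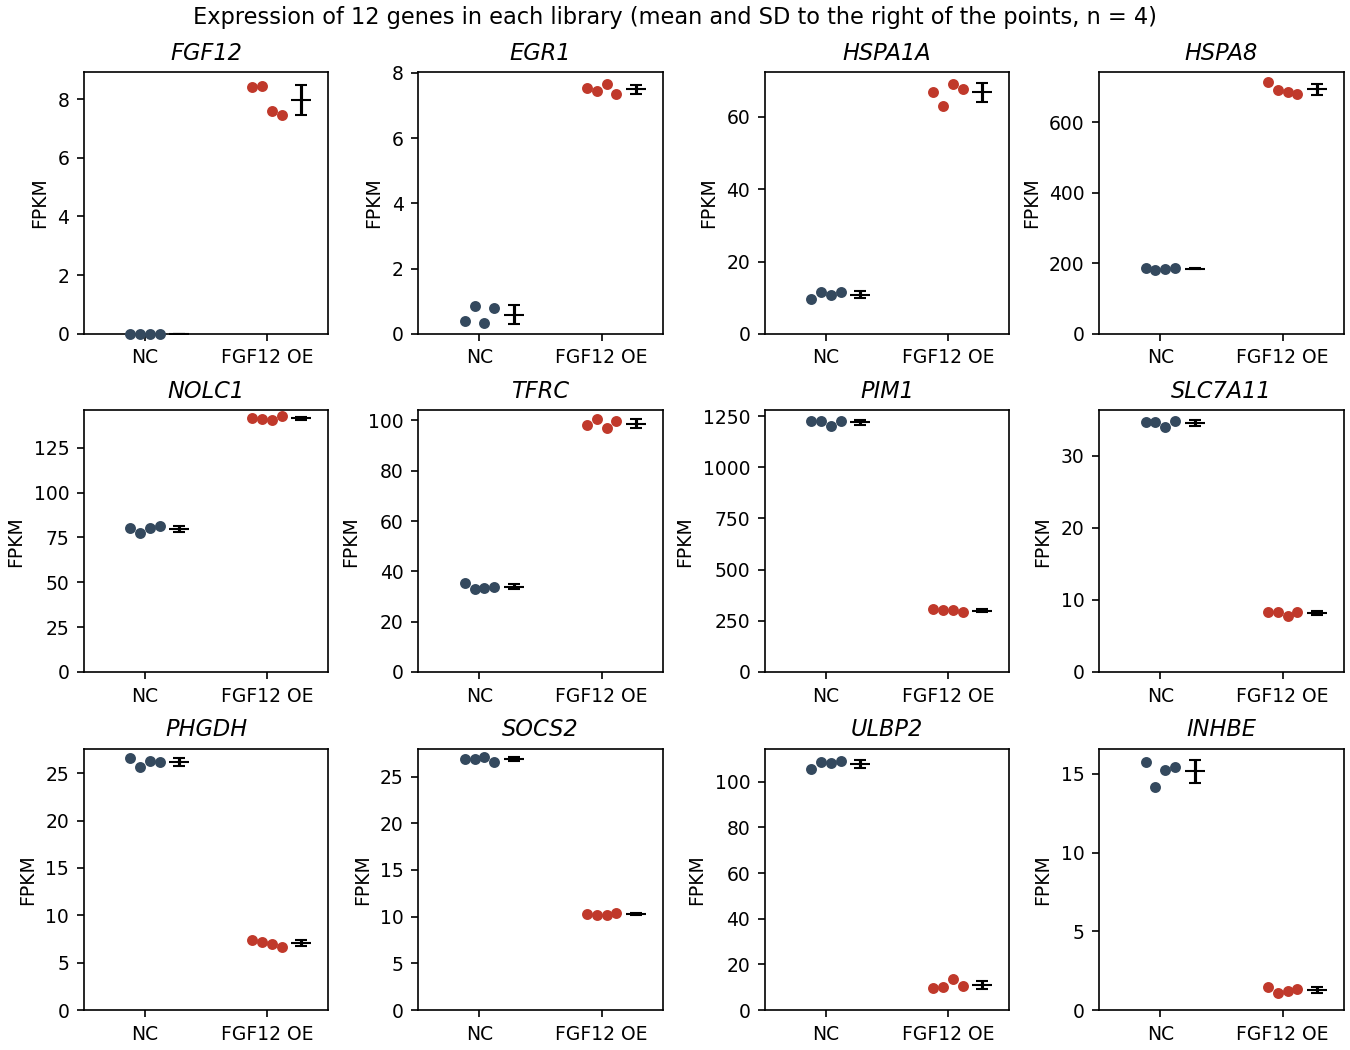
FPKM of 12 genes in each of the 8 libraries, with NC in grey and FGF12 overexpression (FGF12 OE) in red; points are libraries, and the bars to their right give the mean and SD (n = 4). FGF12 was at 0 in all NC libraries, PIM1 fell from 1220 to 300.2 FPKM, and the 2 groups did not overlap in any of these genes.

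Of 11237 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4042 higher and 4032 lower in the FGF12 cells, 71.9% of the genes tested. Most calls were small: 63.4% of them were under 1.5-fold, 386 genes rose at least 2-fold and 627 fell at least 2-fold. At 4-fold or more, the falls were the more numerous, with 116 genes lower and 20 higher. In 7303 genes, 65.0% of those tested, all 4 values of one group lay above all 4 of the other, where chance gives 2.86%. The biological coefficient of variation between libraries of a group was 3.83%, so shifts much smaller than 1.5-fold passed the test.

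**Figure D2:**
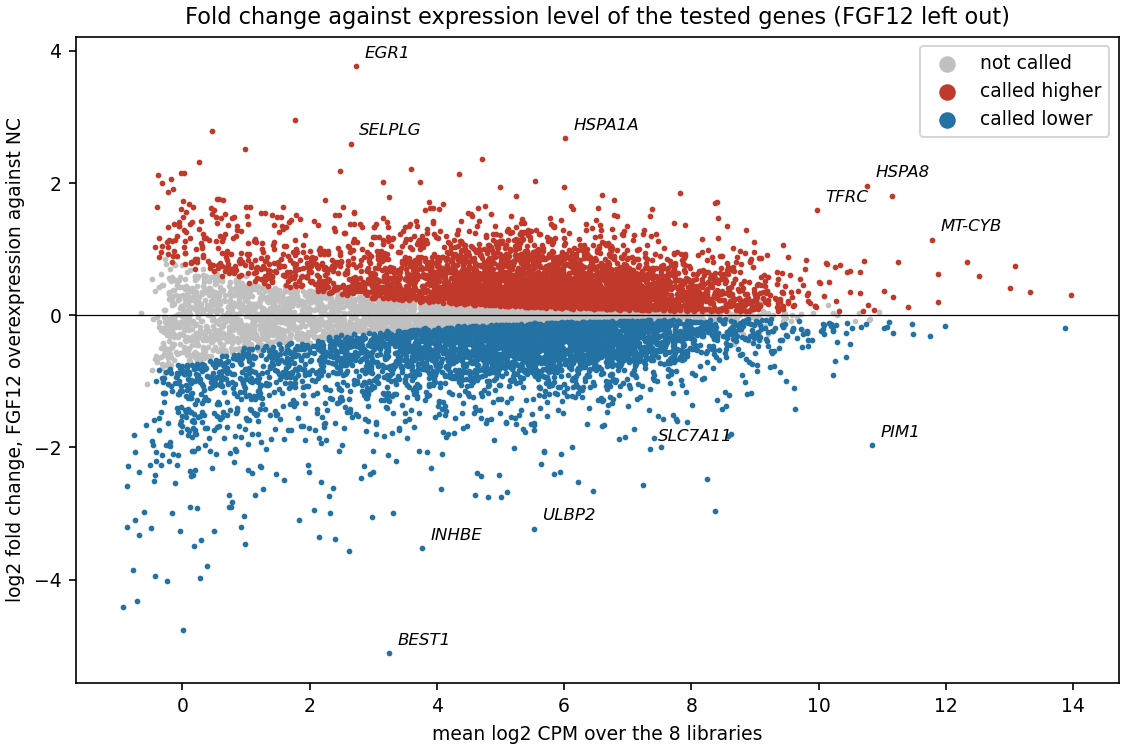
Log2 fold change of each tested gene, FGF12 overexpression against NC, over its mean log2 CPM (counts scaled to library size); red and blue points passed the adjusted threshold as higher (4042, FGF12 itself not drawn) or lower (4032), and grey points did not. EGR1 lies at the top with 3.77 and BEST1 at the bottom with -5.12.

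Among the 10 largest rises, EGR1, an immediate early transcription factor gene, led with a log2 fold change of 3.77 ± 0.15 (SE), from 0.590 ± 0.280 to 7.49 ± 0.129 FPKM (SD, n = 4). F2RL3, which encodes the thrombin receptor PAR4, rose by 2.95 ± 0.18, and SELPLG, the gene of the P-selectin ligand PSGL-1, rose by 2.60 ± 0.12. The inducible HSP70 genes HSPA1A and HSPA1B rose by 2.68 ± 0.05 and 2.36 ± 0.07. These 2 genes are nearly identical in sequence, so the division of reads between them is uncertain. NRROS, ANKLE1, KISS1R, GPR183 and POP1, the last a subunit gene of RNase P and RNase MRP, rose by log2 values of 2.21, 2.18, 2.16, 2.15 and 2.13. The 10 largest falls were led by BEST1, the gene of a calcium-activated chloride channel, at -5.12 ± 0.10, from 6.33 ± 0.0496 to 0.175 ± 0.0331 FPKM. INHBE, an inhibin subunit gene, fell from 15.2 ± 0.711 to 1.28 ± 0.165 FPKM, and ULBP2, which encodes a ligand of the lymphocyte receptor NKG2D, fell from 108 ± 1.67 to 11.1 ± 1.62 FPKM. The cytokine gene OSM fell by 3.26 ± 0.29 on the log2 scale, the netrin receptor gene UNC5B by 3.57 ± 0.14 and the sodium channel gene SCN4A by 3.36 ± 0.15. The others were OR52A5 at -3.98, THRSP at -3.94, YPEL4 at -3.38 and IZUMO1 at -3.10. Single libraries moved 3 of these folds by over 1.5 times: OR52A5 stood at -5.01 without FGF12 overexpression replicate 1, THRSP at -4.63 without FGF12 overexpression replicate 2 and GPR183 at 2.83 without NC replicate 4. The rule of choice required each of these 20 genes to pass the per-gene test and to have no overlap between the groups, so neither is a separate finding. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the highest adjusted p among them was 4.16e-05, for GPR183.

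In 30 gene lists fixed before the data were examined, members were counted by the same per-gene test, and each list was tested against the other genes with camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera called 5 lists higher and 4 lower, and with an estimated correlation it called 1 higher and 1 lower. The calls that held were those of the ribosome biogenesis and the ATF4 lists. Counts of members adjusted over the list alone equalled those over all genes except in 4 lists, where both are given.

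The ATF4 and amino acid response genes showed the most uniform change of the called lists. Of 27 members tested, 26 fell and 0 rose, with a median log2 fold change of -1.43, and camera gave an adjusted p = 4.93e-12 (adjusted p = 0.0195 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, fell from 26.2 ± 0.391 to 7.04 ± 0.316 FPKM (SD, n = 4), and WARS1, the cytosolic tryptophanyl-tRNA synthetase gene, from 207 ± 3.68 to 74.3 ± 1.44 FPKM. The ATF4 transcript itself fell by 0.11 ± 0.03 on the log2 scale, and this gene was singled out after its values were seen.

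Ribosome biogenesis genes rose. Of 27 tested, 22 rose and 2 fell, with a median of 0.69 and a camera adjusted p = 6.75e-06 (adjusted p = 0.0195 with an estimated correlation). POLR1A, the largest subunit of RNA polymerase I, went from 6.27 ± 0.0550 to 13.1 ± 0.209 FPKM, and the nucleolar genes NCL and NOLC1 rose by 0.82 ± 0.03 and 0.88 ± 0.03 on the log2 scale. The 2 members that fell, named after their values were seen, were the RNA helicase gene DDX21 and MYC, a transcription factor that activates this programme, which fell by 0.53 ± 0.03. Cytosolic ribosomal protein genes moved the other way by a small amount: 29 of 49 fell and 2 rose (27 and 2 adjusted over the list alone), with a median of -0.17 and a camera adjusted p = 0.0060 (adjusted p = 0.679 with an estimated correlation). RPLP0 fell from 811 ± 9.87 to 639 ± 26.8 FPKM. As a share of all reads, ribosomal protein genes took 5.61 ± 0.253% in the FGF12 libraries and 6.59 ± 0.294% in NC (SD, n = 4; exact two-sided permutation test, p = 0.0286).

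Mitochondrially encoded transcripts rose in 12 of 13 genes tested and fell in 0, with a median of 0.63 and a camera adjusted p = 0.00264 (adjusted p = 0.611 with an estimated correlation). MT-CYB, a subunit of complex III, went from 2127 ± 168 to 4522 ± 217 FPKM. The mitochondrial share of reads was 7.54 ± 0.362% in the FGF12 libraries and 5.51 ± 0.438% in NC (SD, n = 4; exact two-sided permutation test, p = 0.0286). With quantile-normalized FPKM the list's median was 0.000 and its adjusted p 0.835, the highest of 22 alternatives tested with camera, of which 20 kept the call. Nuclear genes of oxidative phosphorylation were not called as a list (12 of 40 rose and 6 fell, 11 and 5 adjusted over the list alone; adjusted p = 0.373), although UQCRFS1, which encodes the Rieske iron-sulphur subunit, rose by 0.77 ± 0.05 on the log2 scale.

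Genes of the cell division cycle were higher. DNA replication genes rose in 22 of 31 cases and fell in 4 (median 0.31, camera adjusted p = 0.0060; adjusted p = 0.0994 with an estimated correlation), with UHRF1, a maintenance factor of DNA methylation, rising from 10.9 ± 0.557 to 26.2 ± 0.887 FPKM. The replication call was also lost with the stricter filter (median 0.19, adjusted p = 0.0607) and with offsets for GC content and gene length (median 0.21, adjusted p = 0.0543), and 19 of 22 alternatives tested with camera kept it, with adjusted p from 0.00102 to 0.0994. Mitosis genes rose in 20 of 30 cases and fell in 6 (median 0.22, adjusted p = 0.0265; adjusted p = 0.283 with an estimated correlation), with the cyclin gene CCNB1 at 109 ± 5.53 against 55.8 ± 3.50 FPKM. The mitosis call was also lost with every FPKM-based limma fit and with the stricter filter. Replication-dependent histone genes went against the replication list: 16 of 20 fell and 1 rose (median -0.83, adjusted p = 3.55e-04; adjusted p = 0.273 with an estimated correlation). The linker histone gene H1-4 fell by 2.40 ± 0.13 on the log2 scale and H3C10 by 0.81 ± 0.04. Most of these histone transcripts lack a poly(A) tail, so poly(A) selection captures them incompletely.

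Cholesterol synthesis genes rose in 16 of 23 cases and fell in 4 (median 0.38, camera adjusted p = 0.00615; adjusted p = 0.283 with an estimated correlation). The reductase gene DHCR7, which acts late in the pathway, rose from 9.05 ± 0.498 to 21.3 ± 0.325 FPKM (SD, n = 4), and HMGCS1, the gene of an early enzyme, from 19.1 ± 0.316 to 35.1 ± 1.77 FPKM. Adhesion and matrix genes fell in 9 of 13 cases and rose in 1 (median -0.49, adjusted p = 0.0249; adjusted p = 0.212 with an estimated correlation). Among them the transcription factor gene ZEB1 fell by 1.03 ± 0.06 and the integrin genes ITGA5 and ITGAV by 0.85 ± 0.05 and 0.66 ± 0.04. This camera call was also lost without the low-count filter (median -0.093, adjusted p = 0.1395). With the stricter filter it was lost too, although the median did not shrink (-0.526, adjusted p = 0.0679).

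**Figure D3:**
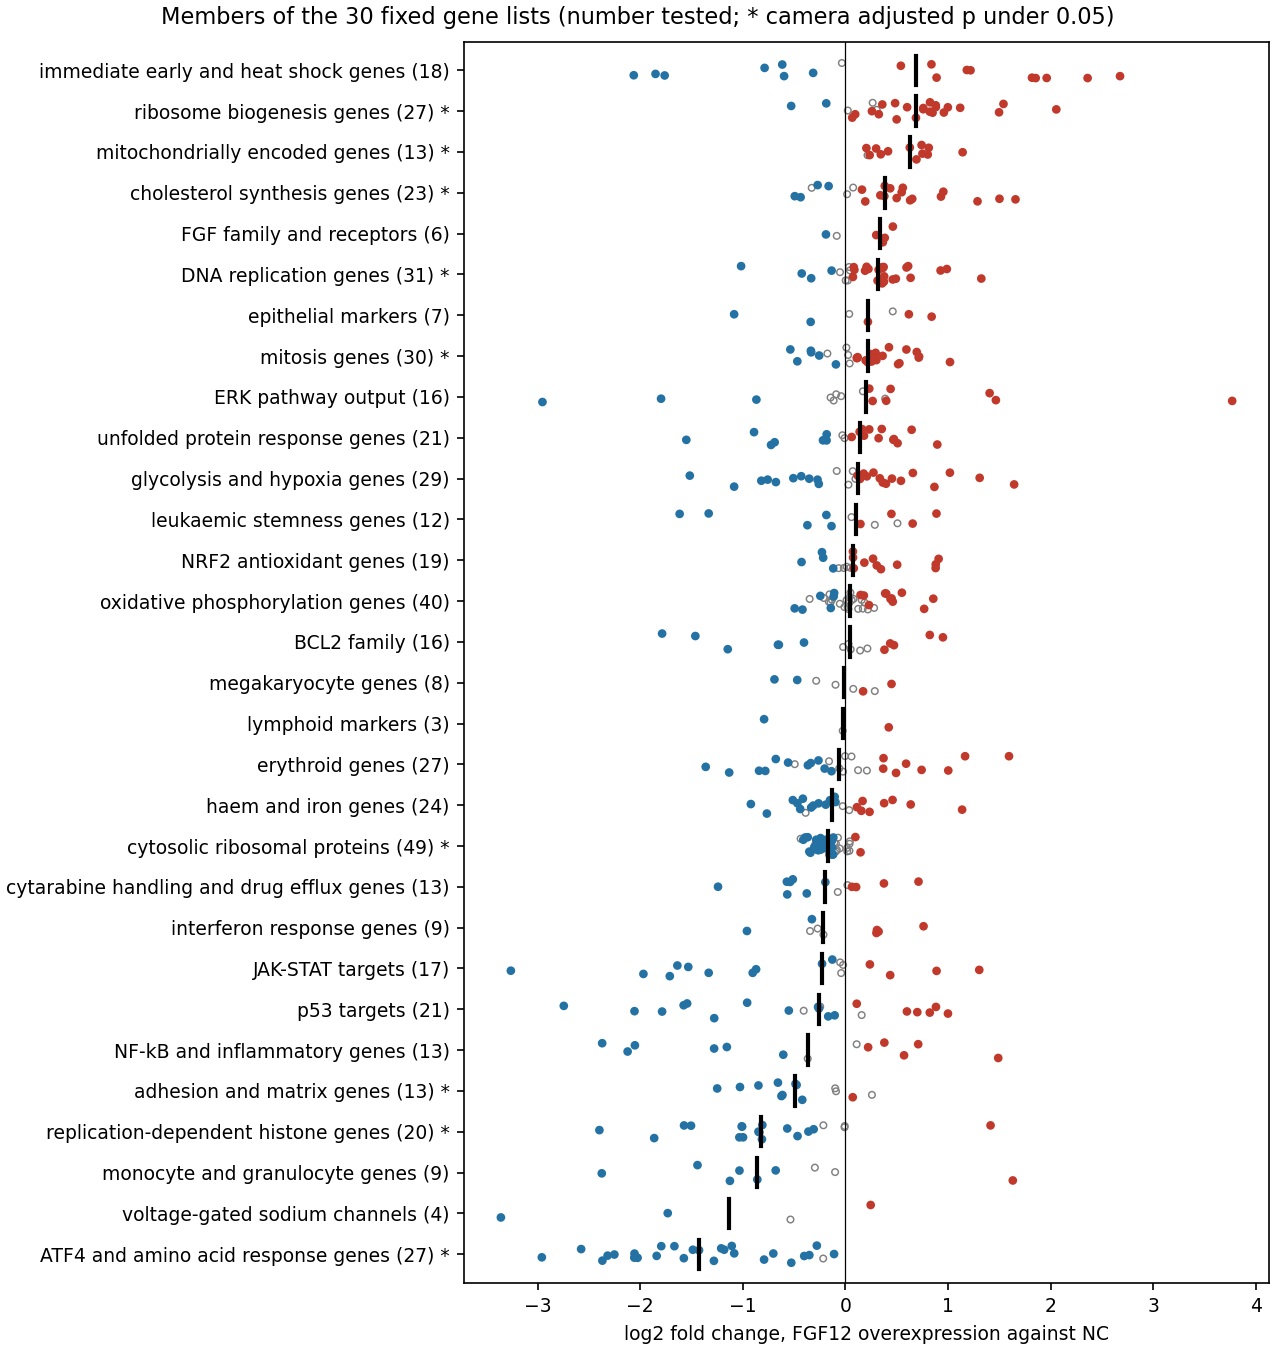
Log2 fold change, FGF12 overexpression against NC, of each tested member of the 30 fixed lists, ordered by the list median (black bar); filled red and blue points passed the per-gene test as higher or lower, open points did not, and an asterisk marks a camera call. The ATF4 list lies lowest with a median of -1.43 and its 26 called members are all below 0.

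JAK-STAT targets fell in 10 of 17 cases and rose in 4, with a median of -0.23, and the list missed the threshold (camera adjusted p = 0.069). Its fallen members included PIM1, the feedback inhibitor SOCS2, from 26.9 ± 0.227 to 10.3 ± 0.111 FPKM (SD, n = 4), and the cyclin gene CCND2, from 11.5 ± 0.254 to 3.83 ± 0.431 FPKM. Camera called the list lower without FGF12 overexpression replicate 1 (adjusted p = 0.0497), where the filter, applied anew, left 11339 genes against 11237. It also called the list lower with offsets for GC content and gene length (adjusted p = 0.00638), an alternative added after the data were seen. Over the 22 alternatives tested with camera the adjusted p ran from 0.00638 to 0.273, the latter with an estimated correlation. ERK pathway output was split, with 7 of 16 higher and 3 lower (adjusted p = 0.378). CCND1, the cyclin D1 gene, rose by 1.47 ± 0.05 on the log2 scale beside EGR1, whereas PHLDA1 fell by 2.95 ± 0.17.

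Heat shock and immediate early genes were fixed as 1 list, of which 10 of 18 rose and 7 fell, and camera did not call it (median 0.69, adjusted p = 0.378). It was called higher on the TPM scale (adjusted p = 0.0417), the lowest of 22 alternatives tested with camera, whose adjusted p reached 0.755. All 7 chaperone genes tested rose, among them HSPH1 by 1.85 ± 0.03 on the log2 scale and HSPA8 by 1.96 ± 0.03. Members of the immediate early part went both ways, with the zinc finger gene KLF6 at -1.85 ± 0.04 and FOS, JUNB and IER2 at 1.22 ± 0.17, 0.89 ± 0.09 and 0.54 ± 0.07. The division of the list into these parts, and the choice of the last 3 genes, were made after the values were seen. Unfolded protein response genes rose in 12 of 21 cases and fell in 7 (adjusted p = 0.618), with PDIA4, an endoplasmic reticulum disulphide isomerase, at 0.90 ± 0.03 and the stress sensor gene ERN1 at -1.55 ± 0.06.

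Markers of blood lineages did not move as lists. Erythroid genes rose in 8 of 27 cases and fell in 11 (adjusted p = 0.919), with TFRC up by 1.59 ± 0.03 on the log2 scale and the carbonic anhydrase gene CA1 down, from 104 ± 1.44 to 38.9 ± 0.337 FPKM. The haem and iron list rose in 8 of 24 cases and fell in 13 (8 and 14 adjusted over the list alone; adjusted p = 0.378), with the ferritin receptor gene NCOA4 at -0.77 ± 0.03 and the ferrireductase gene STEAP3 at 1.14 ± 0.06. Of 8 megakaryocyte genes tested, 2 rose and 2 fell (adjusted p = 0.994), with the tubulin gene TUBB1 at 0.45 ± 0.06 and RUNX1 at -0.69 ± 0.04. In the monocyte and granulocyte list 6 of 9 fell and 1 rose (median -0.86, adjusted p = 0.079), among them the myeloid transcription factor genes SPI1 and CEBPB at -1.12 ± 0.10 and -1.44 ± 0.07. That list was called lower when FGF12 overexpression replicate 1, 2, 3 or 4 or NC replicate 1 was left out (adjusted p from 0.0311 to 0.0494). The filter was applied anew in these fits and left 11308 to 11355 genes, against 11237 in the main fit. The tested members of the list may therefore differ. The list's adjusted p over the 22 alternatives tested with camera ran from 0.0311 to 0.273. Leukaemic stemness genes rose in 4 of 12 cases and fell in 5 (adjusted p = 0.994), and 3 lymphoid markers were tested, of which CD3D rose and NKG7 fell (adjusted p = 0.994). Epithelial markers rose in 3 of 7 cases and fell in 2 (adjusted p = 0.618), with the keratin gene KRT8 at 0.62 ± 0.03.

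Death and stress lists were mixed. Of 21 p53 targets, 12 fell and 6 rose (13 and 6 adjusted over the list alone; camera adjusted p = 0.247), with the cytokine gene GDF15 down from 35.0 ± 3.28 to 5.03 ± 0.499 FPKM (SD, n = 4) and SESN2, which the ATF4 list also holds, at -2.06 ± 0.05 on the log2 scale. The BCL2 family rose in 5 of 16 cases and fell in 6 (adjusted p = 0.994), where the BH3-only genes PMAIP1 and BBC3 fell by 1.15 ± 0.06 and 1.79 ± 0.12. NF-kB and inflammatory genes rose in 5 of 13 cases and fell in 6 (adjusted p = 0.618), with the feedback inhibitor gene TNFAIP3 at -2.37 ± 0.12. Interferon response genes rose in 4 of 9 cases and fell in 2 (adjusted p = 0.858), with BST2 at 0.76 ± 0.04. Glycolysis and hypoxia genes rose in 15 of 29 cases and fell in 10 (adjusted p = 0.373). The glycolytic enzyme genes HK2 and PKM rose by 1.31 ± 0.04 and 1.02 ± 0.03, and the hypoxia target VEGFA fell by 1.52 ± 0.04. NRF2 antioxidant genes rose in 11 of 19 cases and fell in 4 (adjusted p = 0.373), with NQO1 at 0.51 ± 0.05. Genes of cytarabine handling and drug efflux rose in 4 of 13 cases and fell in 7 (adjusted p = 0.494), with the nucleoside transporter genes SLC29A1 and SLC29A2 at -0.54 ± 0.04 and 0.71 ± 0.07.

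Few members of FGF12's own family or of its sodium channel partners were expressed. Apart from FGF12, 6 of the FGF family and receptors were tested, of which 4 rose and 1 fell (median 0.33, camera adjusted p = 0.586), with the receptor gene FGFR3 at 0.46 ± 0.06 on the log2 scale. The homologous factor gene FGF13 fell by 0.19 ± 0.04, a direction that turned to 0.03 with offsets for GC content and gene length. Of 4 sodium channel genes tested, 2 fell and 1 rose (camera adjusted p = 0.351), with SCN4A down by 3.36 ± 0.15 and SCN9A up by 0.25 ± 0.05. In the stemness, BCL2, interferon, unfolded protein response and lymphoid lists the median, the mean and the test differed in sign.

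The calls rest on relative expression within each library. Of the calls, 50.1% were higher with edgeR, 46.1% with limma on log2(FPKM + 1) and 35.2% with limma on log2(TPM + 1), the last 2 over the same 9501 genes, and against edgeR the median gene shifted by -0.05 and -0.16 (log2) in these fits. The angiopoietin gene ANGPT1 rose by 0.17 ± 0.04 on the log2 scale and SCN9A by 0.25 ± 0.05; limma called both on the FPKM scale, at 0.11 and 0.15, and neither on the TPM scale, at 0.01 and 0.08.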

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

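The tests of chaperone genes without HSPA1A and HSPA1B, of immediate early genes, of culture state and of the histone call under offsets were chosen only after the results were seen, as was the list of HSF1 chaperone genes. Bootstrap intervals below resampled the genes of a list 2000 times, as if they were independent. They measure the spread between genes, not between libraries, and are too narrow where the genes of a list move together.

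The highest or lowest of the 4 values of a group stood apart from the other 3, by Dixon's criterion, in 16 of 225 group comparisons of named genes and library measures (7.11%), and chance gives about 1 in 20. The criterion sets the gap against the range of the 4 values, so in tight groups it also flags small differences. NC replicate 1 was the sample in 5 of them: MT-CYB at 1877 FPKM against 2196 to 2237 in the other 3, MT-ATP6 at 2433 against 2797 to 2860, CCNB1 at 60.97 against 53.6 to 54.5, GDF15 at 30.17 against 36.2 to 37.4 and LST1 at 0.6426 against 0.377 to 0.420. NC replicate 3 had OSM at 2.295 FPKM (1.638 to 1.675 in the other 3), PIM1 at 1203 (1224 to 1226) and ITGAV at 7.014 (6.685 to 6.718). NC replicate 2 had WARS1 at 212.9 (204.9 to 206). FGF12 overexpression replicate 3 had GPR183 at 1.786 FPKM (0.8944 to 1.013 in the other 3), SLC7A11 at 7.821 (8.296 to 8.308) and MUC1 at 7.344 (5.873 to 5.978). FGF12 overexpression replicate 1 had OR52A5 at 0.1599 FPKM (0.01565 to 0.03695 in the other 3) and CCND2 at 3.189 (3.997 to 4.108). FGF12 overexpression replicate 2 had THRSP at 0.2154 (0.0596 to 0.06355) and HSPH1 at 51.72 (49.87 to 50.02).

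The gene calls exceeded what other groupings of these libraries gave. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many as 8074 called genes, and the highest of the others gave 0. Only the rank of the real split carries weight here. The other splits put part of the real difference within their groups, which widens the spread, so their 0 is not a chance level. Even the 16 splits that exchanged 1 library per group called 0 genes. For the gene lists, 2 of the 35 splits, the real one included, gave as many as 9 camera calls, the highest of the others giving 9, so this count does not exclude chance for the number of lists called. The other split with 9 exchanged 1 library per group, as did 16 splits in all, which kept part of the real difference and gave 5 to 9, while the 18 splits that exchanged 2 libraries per group gave 0 to 5.

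The fall of the ATF4 and amino acid response genes kept its size in both technical comparisons run. With offsets for GC content and gene length the median was -1.526 (bootstrap 95% interval -1.84 to -1.07), against -1.43 before. The 25 members with no same-strand exon overlap had a median of -1.281 (-1.67 to -0.79). With 26 of 27 members lower, leaving out so few could hardly have removed the fall. The value shows only that the fall was not confined to overlapped members. A difference in culture state at harvest, such as amino acid supply or cell density, remains possible. Culture state and FGF12 overexpression cannot be told apart, because the labels name no culture shared by both groups. In the list's mean, 0 libraries lay inside the other group's range. This decides nothing, as nearly all members had already been called lower and an effect of FGF12 would give the same. An effect of FGF12 itself stays open, as untested.

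Of 25 HSF1 chaperone genes, a list that holds the genes that prompted it, 23 rose and 2 fell, the latter being HSPA4L and HSPA6 (median 0.84). Of the 33 genes of the Gene Ontology term for chaperone-mediated protein folding, 26 rose and 4 fell (camera adjusted p = 0.00248; adjusted p = 0.932 with an estimated correlation). The rise was not confined to HSPA1A and HSPA1B, as the other 23 genes had a median of 0.793 (bootstrap 95% interval 0.49 to 1.22). With 23 of 25 genes higher, leaving out 2 could not have brought the median to 0, so this was no independent test. With offsets for GC content and gene length the median was 0.728 (0.53 to 1.34). Stress during handling may also raise immediate early genes: their median was -0.456 (-1.27 to 0.71), but 4 of 12 rose and 7 fell, which decides nothing, so handling and an effect of FGF12 overexpression cannot be told apart.

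Mitochondrial transcripts were higher while ribosomal protein and histone transcripts were lower (adjusted p = 0.611, adjusted p = 0.679 and adjusted p = 0.273 with an estimated correlation). The ribosomal protein fall did not shrink under offsets for bias from GC content and gene length. Its median was -0.243 (bootstrap 95% interval -0.30 to -0.13) under offsets against -0.17 before. The histone list kept its camera call under the same offsets with the preset correlation (adjusted p = 0.00652; without offsets, adjusted p = 0.273 with an estimated correlation), with a median of -0.812 (-0.95 to -0.36) against -0.83, which argues against this bias as the whole cause; a part is not excluded, as the interval reached past 0.5 times the uncorrected median. Mitochondrial reads in the TMM scaling do not account for the ribosomal protein fall: leaving those genes out moved the median gene by 0.007 and the ribosomal protein median to -0.163 (-0.23 to -0.13). RNA quality values and the efficiency of poly(A) selection were not analysed here.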

How the results depend on the processing

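Scaling to total counts, TMM without the mitochondrial genes and the offsets for GC content and gene length were chosen after the data were seen; the others were fixed before the data were examined. The causes of the changes were not tested, except where fewer genes or a minimum fold follow from the setting itself.

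FGF12 was higher under every alternative that recorded it. The 2-fold minimum, the test against a 1.5-fold threshold and the restriction to protein-coding genes did not. Its lower bound lay between 10.11 and 10.62 on the log2 scale, with 10.59 in the main result. The bound was always computed from counts, with TMM except under total-count scaling. It therefore varies only with the filter, the samples left out and total-count scaling, and does not test the other alternatives. Calls fell from 4042 higher and 4032 lower to 386 and 627 with a 2-fold minimum, to 867 and 989 in the test against a 1.5-fold threshold, and to 2650 and 2676 with the stricter filter, which left 6544 genes. On the TPM scale 2575 genes were higher and 4734 lower. Leaving out each sample in turn gave 3906 to 3994 higher and 3907 to 3998 lower calls. The lists called went from 5 higher and 4 lower to 1 and 1 with an estimated correlation, 12 and 15 with fry, which tests each list on its own, 3 and 3 with the stricter filter, and 3 and 4 with quantile normalization. With the replicate number as a block, 4050 genes were higher and 4036 lower, 5 lists higher and 5 lower, the added one being the monocyte and granulocyte list (median -0.885, adjusted p = 0.0447). The same-numbered libraries did not pair: their deviations correlated at 0.08, -0.07, 0.03 and 0.01 for numbers 1 to 4, and not every library correlated best with its own number.

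Of 2186 values of single named genes under the alternatives, 2178 kept direction and side of the threshold, 4 lost the call and 4 turned. FGF13 turned to 0.025 with offsets, and F12, never called, turned to -0.068 with offsets and ranged from -0.180 to 0.290 without 1 sample. Of 676 list values, 595 kept both, 18 lost the call, 26 gained it and 37 changed camera's or fry's direction. The lists that turned were called in neither setting, except the unfolded protein response with fry (median 0.139, adjusted p = 0.00116). Their medians were as follows. Leukaemic stemness genes stood at 0.107 with the block, 0.150 without a filter, 0.049 with total-count scaling, 0.200 with offsets and 0.072 to 0.119 without 1 sample. Lymphoid markers stood at -0.013 with the block, -0.018 without mitochondrial genes in TMM, -0.187 with offsets and -0.192 to 0.324 without 1 sample. Megakaryocyte genes stood at 0.083 without a filter, 0.133 with the stricter one, 0.007, -0.015 and -0.019 in log2 FPKM with pseudocounts of 1, 0.1 and 0.01, 0.056 with quantile normalization and -0.116 to 0.042 without 1 sample. NF-kB genes stood at 0.115, 0.174 and 0.183 with these pseudocounts, 0.188 with quantile normalization and 0.066 with TPM. The BCL2 family stood at -0.128 with TPM, -0.014 with total-count scaling and -0.001 to 0.078 without 1 sample. With offsets, interferon response genes stood at -0.142, glycolysis and hypoxia genes at 0.050 and epithelial markers at 0.179. At 11488466 to 15817220 counts per library, 66.0% of genes changed 1.2-fold were recovered on simulated data, in which far fewer genes changed than were called here.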

Other observations

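RNA-processing genes rose beyond the fixed lists. Of 1971 biological process terms of the Gene Ontology, camera with the preset correlation called 19 higher and 0 lower after Benjamini-Hochberg adjustment, and with an estimated correlation it called 0. Splicing by the spliceosome led: 118 of its 176 tested genes rose and 23 fell, with a median log2 fold change of 0.34 (adjusted p = 1.05e-06; adjusted p = 0.254 with an estimated correlation). In rRNA processing 110 of 153 genes rose and 22 fell (median 0.39, adjusted p = 1.74e-06; adjusted p = 0.254 with an estimated correlation), and in tRNA processing 68 of 104 rose and 19 fell (median 0.34, adjusted p = 0.00862; adjusted p = 0.873 with an estimated correlation). Mitochondrial translation genes, which are nuclear, rose in 55 of 91 cases and fell in 11 (median 0.25, adjusted p = 0.0290; adjusted p = 0.937 with an estimated correlation). Nucleocytoplasmic transport genes rose in 34 of 52 cases and fell in 8 (median 0.23, adjusted p = 0.0455; adjusted p = 0.932 with an estimated correlation).

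Several genes that dividing cells use heavily had low values in all libraries, a pattern noticed in the data and tested only afterwards. ALDOA, the main glycolytic aldolase, averaged 0.296 FPKM over the 8 libraries, NOP2 0.204, NUSAP1 0.231 and CYP51A1 0.391. In GENCODE release 29, other genes on the same strand cover 42.3%, 54.4%, 62.2% and 79.3% of their exonic bases. A candidate explanation is that reads in such overlaps were left out of the counts. ALDOA, NOP2, NUSAP1 and PPAN had prompted the test and were left out of it. Among the remaining members of 6 fixed lists, 1 of 4 genes overlapped over at least 25% of their exonic bases averaged under 1 FPKM, against 8 of 174 others. This decides nothing (Fisher's exact test, two-sided, odds ratio 6.748, 95% interval 0.117 to 96.1, p = 0.189), and the rule for reading it was set after a first run that held all 8 overlapped genes. Among the other protein-coding genes the odds ratio was 7.16 (6.03 to 8.55), though overlapped genes there may also be less expressed for other reasons. Fold changes of these genes, such as 2.06 ± 0.40 (SE) for NOP2, rest on few reads, which may come from only a part of the gene.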
